A study of Homo sapiens with 3 samples.

How the data were processed

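Total RNA of BEAS-2B cells treated with MTX and of cells treated with DMSO was measured on 3 two-colour arrays. MTX is given here as the labels write it. The labels put the treated RNA in the Cy5 channel and the DMSO RNA in the Cy3 channel of every array, so each array is 1 ratio, the 3 arrays form a single group, and no dye swap exists. A gene-specific dye effect is therefore part of every value. The array numbers 1 to 3 come from the sample titles.

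Per the series' design text, RNA was labelled with a FairPlay kit, slides were read with a GenePix scanner and its software, the local median background was subtracted, and intensity-dependent LOWESS normalisation was applied. That text names a significance analysis of microarrays without its settings. The deposited table holds 1 normalised log ratio per probe and array. Its scale is not stated, and log10 was taken as the working unit of the deposited values for thresholds in folds. The spread between spots of the same accession had a median SD of 0.0751, 0.0525 and 0.0422 on arrays 1, 2 and 3. This is 18.9%, 12.8% and 10.2% if the values are log10 and 5.34%, 3.71% and 2.97% if they are log2, and neither is excluded. The p-values do not depend on the base. The design had foreseen the log2 scale, and the values were used in their deposited units instead. The direction of the ratio could not be set against scanner values, which were not used here, and positive values were read as higher with MTX from the dyes in the labels. The columns had medians of 0.00137, 0.00222 and 0.00194, so the arrays are centred close to 0, and they were used as deposited. Since only ratios were used, background correction, a filter on dim probes, normalisation from intensities and a slide effect could not be varied.

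The table has 31615 probes, of which 17569 had a value on 3 arrays, 5670 on 2 and 8376 on 1. Spots with a value numbered 21224, 25272 and 25927 on the 3 arrays. The platform annotation gave 1 gene symbol for 22472 probes, several for 80 and none for 9063. The Entrez identifiers of 22444 probes were found in the RefSeq gene table, and 0 symbols changed. Probes with several symbols were not used to name a gene. For the fit over genes, the 13027 probes with 1 symbol and a value on all 3 arrays were averaged per gene and array, which gave 9394 genes, 2458 of them with more than 1 probe. Of the 672 called genes with more than 1 probe, 92 had probes whose means differ in sign. The 4495 complete probes without a symbol and the 47 with several entered only the fit over single probes.

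The mean log ratio of each gene was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. The same fit over the 17569 single probes called 5350, 2675 higher and 2675 lower. Errors are SDs over the 3 arrays. The number of arrays limits the precision, and their independence is not stated. Gene lists were tested with camera of limma at a preset correlation of 0.01 against all other genes, with adjustment over the 27 lists, each with at least 5 measured genes. Beside it stand the counts of members past the threshold over all genes and with p-values adjusted over the list alone. Pairs of arrays were compared by Pearson correlation across genes. Figures were drawn with matplotlib 3.10.9.

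Before the data were examined, the tests, the alternatives, the 27 lists and the rule for named genes were fixed. The rule takes the 12 highest and the 12 lowest means among called genes of 1 sign on all 3 arrays, without locus-only symbols, the 3 members of each list with the smallest p, and 12 genes whatever their values. Of these 12, 1 is not reported here, and the others are TYMS, FPGS, GGH, SLC19A1, ABCG2, TOP2A, TOP2B, CDKN1A, MDM2, PCNA and MKI67. SLC19A1 was not analysed here, and FPGS, ABCG2 and TOP2A had values on 2 arrays only, so they entered only the fit of probes with values on at least 2 arrays. CDKN1A and MDM2 each rest on the probe with values on all 3 arrays, since their second probe lacked some. On array 2 the second probe of CDKN1A gave -0.0345, against 0.407 for the probe used. Members named because a list had 5 or fewer called genes in a direction, and the further MCM genes, CXCL8 and IL1A, were chosen after their values were seen. Some genes belong to more than 1 list.

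The scripts were tested on simulated data with 9394 genes, of which 200 were changed. With 3 arrays 13% of changes of 0.15 and 57% of changes of 0.30 were recovered, with 1 false call, and with 2 arrays 0% of either. In the data 29.0% of genes were called, a larger share than was changed here, so these rates need not hold for them. Another simulation gave every gene its observed mean. With 3 arrays it called 4065 genes, 22 of them with the wrong sign, and with 2 arrays it called 0. A simulated list shifted by 0.1 had an adjusted p of 4.56e-21 with the preset correlation and 0.346 with an estimated one. Alternatives covered the centring, scaling and weighting of arrays, the spread model, missing values, the averaging of probes, probes of wide range, each array left out in turn, other thresholds, a SAM-type one-class test, a plain one-sample statistic and other tests of lists. A local mean over neighbouring spots (lines of 215 spots, a kernel SD of 2 spots), the average of arrays 1 and 2, and the comparison of ribosomal proteins with other abundant genes were added after the data had been seen.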

Results

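BEAS-2B cells, an immortalised line of human bronchial epithelium, were exposed to MTX or to the vehicle DMSO, and their total RNA was compared on 3 arrays of the whole human genome. MTX was given at 0.144 µM, described as the concentration giving 20% inhibition, for 48 h after a 24 h incubation. Each array carried RNA of treated cells labelled with Cy5 and RNA of DMSO cells labelled with Cy3, so that 1 group of 3 ratios was obtained and no array had the dyes exchanged. Values were given for 21224, 25272 and 25927 probes on arrays 1, 2 and 3, and 17569 probes had a value on all 3. These covered 9394 genes with a single symbol. No depth applies to such ratios, and the number of arrays limits the precision. All signed values below are log ratios in deposited units, in which a positive value is taken as higher with MTX. This direction is likely rather than settled: it rests on the labelled dyes and on the usual order of Cy5 over Cy3. The base of the logarithm is not stated, so folds are given on the base 10 reading, with the base 2 reading beside some of them.

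The comparison asked which genes differed between MTX-treated and DMSO-treated bronchial cells. A broad change was measured, with 1557 genes higher and 1169 lower among the 9394 tested (2726 genes, 29.0%, limma adjusted p under 0.05). Lists of p53 targets and immediate-early factors were higher, and lists of ribosomal proteins, histones and the respiratory chain lower, by camera with a preset correlation. With an estimated correlation their adjusted p-values were 0.657, 0.732, 0.420, 0.732 and 0.667. With 3 arrays this test also missed a simulated list shifted by 0.1, so failing it does not tell that a list is unchanged. The simulated genes were drawn independently of each other, so that loss did not come from correlation between genes. For ribosomal proteins and the respiratory chain the estimated correlations were -0.0183 and -0.0203, below the preset 0.01. Correlation between genes therefore does not explain the loss of either list. For p53 targets, histones and immediate-early factors the estimates were 0.0454, 0.131 and 0.0882. A part played by correlation stays open for these lists. Most changes were small. At least 2-fold changes, if the values are base 10 logs, were found for 91 of the higher and 33 of the lower genes, against 0 and 0 if they are base 2 logs. All 2726 genes had the same sign on all 3 arrays, which a call on 3 arrays nearly requires. Of all genes, 5971 did (63.6%, against 25% by chance for independent signs). A dye effect or a spot deviation shared by arrays would also raise this share, so it does not by itself point to MTX. The labels do not say that the arrays came from separate cultures, nor whether the DMSO RNA was a single pool. The p-values therefore measure the spread between these 3 arrays, which may be technical, and would leave out the spread of the control if it was a single pool. Without array 1 or array 2 the limma fit called 0 genes, with 2938 and 2387 at an unadjusted p under 0.05, and without array 3 it called 4287 genes.

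IL1B, the gene of the inflammatory cytokine interleukin-1 beta, had the highest mean log ratio of the called genes, 0.713 ± 0.0443 (SD, n = 3), which is 5.17-fold if base 10 and 1.64-fold if base 2. ACER2, an alkaline ceramidase, reached 0.674 ± 0.102, or 4.72-fold against 1.60-fold. KBTBD8, a substrate adaptor of a ubiquitin ligase, reached 0.650 ± 0.123, or 4.47-fold against 1.57-fold. TP53I3, a p53-induced quinone oxidoreductase, averaged 0.603 ± 0.350 and was uneven, at 0.797 and 0.813 on arrays 1 and 2 and 0.198 on array 3. With the local mean of the array surface removed, its mean was 0.370, and with probes on at least 2 arrays it lost its call (adjusted p = 0.0558). DUSP1, a phosphatase of MAP kinases, rose by 0.582 ± 0.0758, or 3.82-fold. PPM1D, the phosphatase WIP1 that dampens p53 signalling, rose by 0.568 ± 0.0430, or 3.70-fold. The death receptor gene FAS rose by 0.562 ± 0.0185, or 3.65-fold. The other members of the 12 highest were the kinase SGK1 (0.568 ± 0.105), the cytokine IL11 (0.532 ± 0.174), the chromatin-binding factor ARID5B (0.498 ± 0.0589), the zinc-finger gene ZNF670 (0.492 ± 0.196) and the EGF receptor ligand EREG (0.480 ± 0.0635). When probes with values on at least 2 arrays were used, ARID5B had a mean of 0.210 and an adjusted p of 0.133. Further probing of this gene, by spots with values on only 2 arrays, thus read lower than the probe used. ZNF670 had a mean of 0.312 after removal of the local mean.

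At the other end, RPS6KA2, a ribosomal S6 kinase, had the lowest mean, -0.543 ± 0.143 (SD, n = 3), or 3.49-fold lower if base 10 and 1.46-fold if base 2. TMSB4X, which encodes an actin-sequestering peptide, lay at -0.417 ± 0.0316, or 2.61-fold lower. The replicative helicase subunit MCM2 fell to -0.379 ± 0.10, or 2.39-fold lower, and the ribosomal protein gene RPS19 to -0.378 ± 0.0773. LMNB1, the gene of the nuclear lamina protein lamin B1, lay at -0.375 ± 0.0795, or 2.37-fold lower. The branched-chain aminotransferase gene BCAT1 (-0.353 ± 0.0241), the proteasome subunit PSMA7 (-0.351 ± 0.0313) and the nuclear receptor NR1D2 (-0.370 ± 0.0281) were lower by similar amounts on each array. Among the same 12 were the serum amyloid gene SAA2 (-0.372 ± 0.10), the protease KLK5 (-0.402 ± 0.260), the homeobox gene HOXC6 (-0.385 ± 0.225) and the orexin receptor HCRTR2 (-0.349 ± 0.195). KLK5, HOXC6 and HCRTR2 were much nearer to 0 on array 3, at -0.120, -0.126 and -0.131. Their adjusted p-values of 0.0419, 0.0342 and 0.0315 became 0.0681, 0.0577 and 0.0546 when probes with values on at least 2 arrays entered the fit. After removal of the local mean HOXC6 averaged -0.219, and HCRTR2 averaged -0.206 with an adjusted p of 0.0503.

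**Figure D1:**
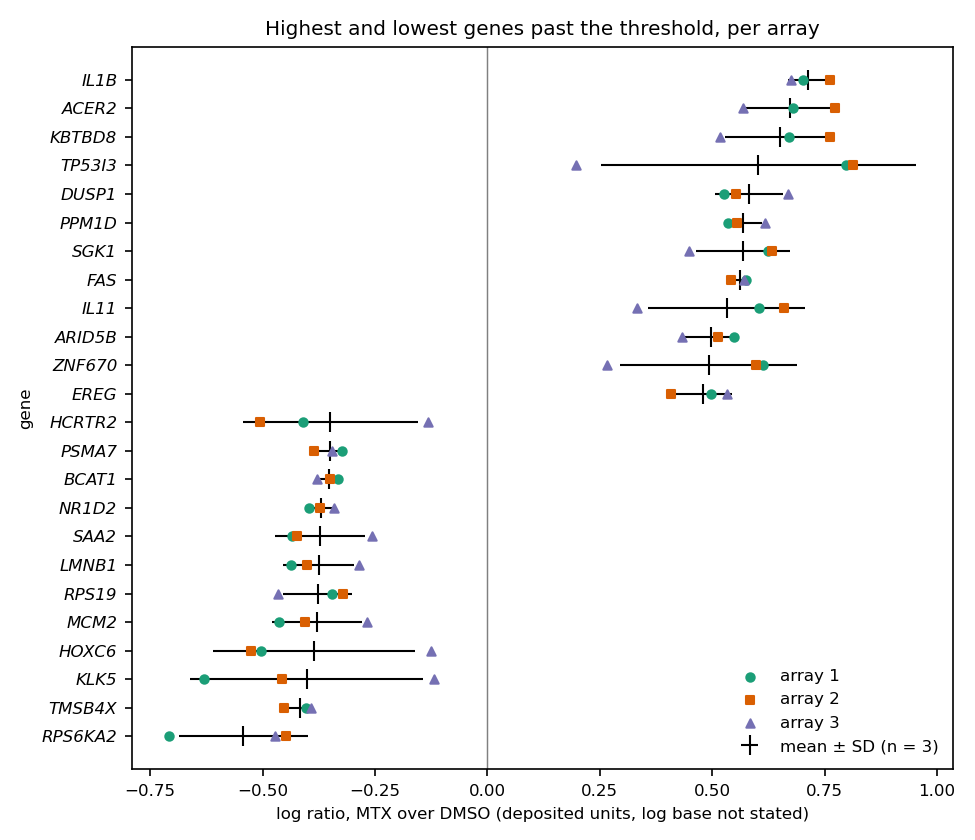
Log ratio of MTX over DMSO (x axis, deposited units) for the 12 highest and 12 lowest called genes (y axis), with symbols for arrays 1, 2 and 3 and bars for the mean ± SD (n = 3). IL1B and FAS lie close together on the 3 arrays, whereas TP53I3 reaches 0.797 and 0.813 on arrays 1 and 2 and 0.198 on array 3.

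p53 target genes were higher with MTX. Of 23 measured members 16 rose, 1 fell and 6 did not pass (20 higher and 1 lower adjusted over the list alone). The list's median was 0.215 ± 0.0228 (SD of the 3 array medians), or 1.64-fold if base 10, and the list stood apart from all other genes with a camera adjusted p of 3.27e-07. With an estimated correlation between its genes the adjusted p = 0.657. Besides FAS, PPM1D and TP53I3, the ribonucleotide reductase subunit RRM2B rose by 0.312 ± 0.0391 (n = 3). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 0.393 ± 0.0814, or 2.47-fold, on the probe with values on all 3 arrays, while its other probe, measured on array 2 alone, gave -0.0345. MDM2, the ubiquitin ligase of p53, rose by 0.409 ± 0.126, or 2.56-fold. BAX, a pro-apoptotic member of the BCL2 family, was the member that fell, at -0.124 ± 0.0323, and was picked out after its value was seen. Among 23 apoptosis regulators 5 rose and 2 fell (6 and 4 adjusted over the list alone). BIRC2 and BCL2A1, both known as inhibitors of cell death, rose by 0.292 ± 0.0297 and 0.291 ± 0.0451. FAS and TNFRSF10B, both death receptors held by the p53 list too, rose, as did cytochrome c (CYCS, 0.168 ± 0.0284). BAX and BID fell, and this list did not stand apart (adjusted p = 0.587). DNA damage signalling and repair had 4 higher and 3 lower of 31 genes (4 and 2 adjusted over the list alone, camera adjusted p = 0.587). There the base excision glycosylase TDG rose by 0.228 ± 0.0198 and the nuclease EXO1 by 0.117 ± 0.00571, with RAD51AP1 and LIG4. The uracil glycosylase UNG fell to -0.194 ± 0.0620, with PRKDC and XRCC6. TNFRSF10B, CYCS, BID, RAD51AP1, LIG4, PRKDC and XRCC6 were named after their values were seen. The 3 probes of TDG ranged from 0.0364 to 0.341, and its first probe alone did not pass (adjusted p = 0.260). For EXO1 the first of 10 probes gave 0.0843 (adjusted p = 0.0561).

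Genes of DNA replication went both ways. MCM2 and MCM5, subunits of the replicative helicase, fell to -0.379 ± 0.10 and -0.264 ± 0.0328 (n = 3). The 4 remaining subunits of the same ring, MCM3, MCM4, MCM6 and MCM7, also passed, at -0.101, -0.226, -0.182 and -0.180, and were named after their values were seen. MCM4 was uneven, at -0.305 and -0.319 on arrays 1 and 2 and -0.0535 on array 3, with an adjusted p of 0.0488. UHRF1, which recruits the maintenance DNA methyltransferase, rose by 0.183 ± 0.0350, although it averaged 0.0721 (adjusted p = 0.10) after the local mean was removed. In total 6 genes of this G1/S list rose and 7 fell of 29 (7 and 7 adjusted over the list alone, camera adjusted p = 0.746). The sliding clamp PCNA averaged 0.0562 ± 0.0263 and did not pass (adjusted p = 0.113). Removal of the local mean gave it 0.111 (adjusted p = 0.0158), and array weights gave 0.0634 (adjusted p = 0.0162). Of the mitotic genes 10 of 31 were higher and 1 lower, both over all genes and adjusted over the list alone. The mitotic kinase CDK1 and its binding partner CKS2 rose by 0.166 ± 0.0291 and 0.172 ± 0.0134. The cytokinesis motor KIF23 rose by 0.177 ± 0.0344 and the proliferation marker MKI67 by 0.131 ± 0.00806. Cyclin A2 (CCNA2) was the member that fell, at -0.0795 ± 0.0106, and was named after its value was seen. As a list, G2/M and mitosis did not pass (adjusted p = 0.126). Core and linker histones, the proteins that package DNA, had 1 higher and 8 lower of 17 genes (1 and 9 adjusted over the list alone). Their median was -0.101 ± 0.0138, with a camera adjusted p of 0.0271, against an adjusted p = 0.732 with an estimated correlation and 0.0875 without array 3. H3-3B, H3C4 and H4C3 fell to -0.216 ± 0.0346, -0.186 ± 0.0218 and -0.227 ± 0.0816, and H2BC13, named after its value was seen, rose by 0.144 ± 0.0459. Whether a probe tells apart the near-identical histone genes was not tested.

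Genes of cytosolic ribosomal proteins were lower as a group. Of 41 measured members 0 rose and 25 fell (0 and 26 adjusted over the list alone), with a median of -0.131 ± 0.00653 (SD of the 3 array medians), 1.35-fold lower if base 10. The camera adjusted p was 5.92e-10, and with an estimated correlation the adjusted p = 0.420. RPS16, RPL7A and RPL4 fell to -0.312 ± 0.0324, -0.245 ± 0.0220 and -0.221 ± 0.0151, and the first probe of RPL7A alone gave -0.147. Other abundant transcripts, a comparison chosen after the ribosomal result was seen, also lay low. Of 65 measured, 23 were lower and 1 higher, with a median of -0.0611. They came from a fixed list of 72 gene names and not from intensities, so their abundance in these cells was not measured. Only the ribosomal proteins tested here were taken out, so members of the respiratory chain list may be among them. MYC, a transcription factor that drives growth genes, fell to -0.184 ± 0.0429, and its target CDK4 to -0.201 ± 0.00489. Together with ribosome biogenesis factors, 9 of 22 genes of that list fell and 2 rose (9 and 3 adjusted over the list alone, camera adjusted p = 0.0741). The helicase DDX21 (0.206 ± 0.00898) and NOP2, named after its value was seen, were the genes that rose. Of 30 genes of the mitochondrial respiratory chain, 8 fell and 2 rose, both over all genes and adjusted over the list alone. The ATP synthase subunit ATP5F1A fell to -0.197 ± 0.0139, the complex I subunit NDUFB10 to -0.254 ± 0.0603 and the cytochrome oxidase subunit COX5B to -0.155 ± 0.0258, whereas ATP5PB and SDHA, named after their values were seen, rose. The median was -0.0493 ± 0.0206 (camera adjusted p = 0.0271, and adjusted p = 0.667 with an estimated correlation). Without array 3 the adjusted p of this list was 0.0852, and against random lists it was 0.0549. Its median was no lower than the -0.0611 of the other abundant transcripts. A low reading of abundant transcripts therefore cannot be told apart for this list.

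In the unfolded protein and ATF4 response 5 of 29 genes fell and 2 rose, over all genes and adjusted over the list alone. SLC7A5, a transporter of large neutral amino acids, fell to -0.334 ± 0.0633 (n = 3), the secreted glycoprotein STC2 to -0.220 ± 0.0201 and the pseudokinase TRIB3 to -0.176 ± 0.00988. ASNS and CEBPB also fell and DNAJB9 and ATF3 rose, all 4 named after their values were seen. This list had a camera adjusted p of 0.0561. Heat shock proteins included 2 higher and 1 lower of 15 genes (1 and 1 adjusted over the list alone, camera adjusted p = 0.746). DNAJB4 rose by 0.170 ± 0.0302, HSPA4 fell to -0.114 ± 0.0160 and HSPH1 averaged 0.162 ± 0.102 with an adjusted p of 0.0498. HSPH1 lost its call with centred arrays (adjusted p = 0.0508), with scaled arrays (0.0515), with the robust spread model (0.0519), with the first probe of each gene (0.0533), with probes on at least 2 arrays (0.0785) and without array 3 (0.0597), besides the fits that called 0 genes. The first of 2 probes of HSPA4 gave an adjusted p of 0.0530. Hypoxia and glycolysis genes split, with 5 of 25 higher and 4 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.746). The vasodilator peptide gene ADM rose by 0.311 ± 0.0393 and the mitophagy receptor BNIP3 by 0.164 ± 0.0139, with KDM3A, HK2 and ANGPTL4. The glycolytic enzyme ENO1 fell to -0.151 ± 0.0230, with PKM, GAPDH and GPI, which like the preceding 3 were named after their values were seen. NRF2 and oxidative stress genes gave 3 higher and 3 lower of 17 (3 and 4 adjusted over the list alone, camera adjusted p = 0.587). The ferritin light chain gene FTL fell to -0.170 ± 0.0126, and GCLC, a subunit of the enzyme that limits glutathione synthesis, rose by 0.0994 ± 0.0265. Its first probe alone gave 0.0536 (adjusted p = 0.239), and 0.0773 (adjusted p = 0.0517) was obtained after removal of the local mean. SOD2 averaged -0.0938 ± 0.0205, but its 3 probes ran from -0.184 to 0.0109, and the first of them was the positive one. With probes on at least 2 arrays GCLC and SOD2 had adjusted p-values of 0.0599 and 0.0620. GCLM and HMOX1 (higher) and PRDX1 (lower) were named after their values were seen.

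Among 15 measured genes of folate and one-carbon metabolism, 2 rose and 2 fell, over all genes and adjusted over the list alone. TYMS, thymidylate synthase, rose by 0.143 ± 0.0534 (n = 3, adjusted p = 0.0254), or 1.39-fold if base 10. The mitochondrial folate carrier SLC25A32 rose by 0.0988 ± 0.0283, with an adjusted p of 0.0620 when probes on at least 2 arrays were used and a mean of 0.168 (adjusted p = 0.00728) after removal of the local mean. ATIC and GART, enzymes of purine synthesis that use folate cofactors, fell to -0.154 ± 0.0669 and -0.0912 ± 0.0238, GART being named after its value was seen. The camera adjusted p was 0.587. GGH, a folate hydrolase, averaged 0.0413 ± 0.0719 (adjusted p = 0.382), with 0.00378, -0.00411 and 0.124 on the 3 arrays. Without array 3 its mean was -0.000164, and after removal of the local mean it passed at 0.115 (adjusted p = 0.0228). FPGS was measured on arrays 1 and 2, at 0.0316 and 0.0225, while the transporter ABCG2 (0.0374 and 0.00527) and the topoisomerase TOP2A (0.0897 and 0.0342) were measured on arrays 2 and 3. In the fit of probes on at least 2 arrays their adjusted p-values were 0.560, 0.658 and 0.268. TOP2B averaged -0.0405 ± 0.0177 and did not pass (adjusted p = 0.192). SLC19A1 was not analysed here. Purine synthesis and salvage had 2 higher and 4 lower of 13 (2 and 5 adjusted over the list alone, camera adjusted p = 0.587). The salvage enzyme HPRT1 rose by 0.126 ± 0.00266, with ADA, and PAICS fell to -0.113 ± 0.0382, with PFAS and the same ATIC and GART. ATIC and PAICS had adjusted p-values of 0.0520 and 0.0564 with probes on at least 2 arrays. Pyrimidine and deoxynucleotide synthesis had 6 higher and 2 lower of 15, over all genes and adjusted over the list alone (camera adjusted p = 0.587). The reductase subunits RRM2B and RRM1 (0.182 ± 0.0480) rose, as did the nucleotide kinase CMPK1 (0.202 ± 0.0212), and NME1 and NME2 fell. ADA, PFAS, NME1 and NME2 were named after their values were seen.

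Immediate-early transcription factors and their feedback phosphatases were higher, with 10 of 20 rising and 2 falling, over all genes and adjusted over the list alone. The median was 0.0856 ± 0.0154 (camera adjusted p = 0.0271, and adjusted p = 0.732 with an estimated correlation). EGR1, a zinc-finger factor induced by growth signals, rose by 0.340 ± 0.0536 (n = 3), or 2.19-fold if base 10, and the AP-1 subunit JUND by 0.200 ± 0.00620. MYC and SRF, the latter named after its value was seen, fell. Without array 3 the list's adjusted p was 0.111. Cytokines, chemokines and NF-kappaB targets contained 7 higher and 5 lower of 20 genes (8 and 6 adjusted over the list alone) and did not stand apart (camera adjusted p = 0.566). Next to IL1B and IL11, the interleukin gene IL6 and the neutrophil chemokine CXCL1 each rose by 0.245, with SDs of 0.0341 and 0.0402. CXCL8 (0.369 ± 0.10) and IL1A (0.349 ± 0.130) rose too, and TNFAIP2, NFKBIA, CXCL5, CCL2 and CXCL3 fell, all 7 named after their values were seen. Interferon-stimulated genes had 3 higher and 1 lower of 16, over all genes and adjusted over the list alone (camera adjusted p = 0.746). The exonuclease ISG20 rose by 0.137 ± 0.0389, the RNA sensor RIGI by 0.104 ± 0.0260 and IRF7, named after its value was seen, also rose. IFI27 averaged -0.112 ± 0.0441 over 11 probes whose means ran from -0.244 to 0.114. RIGI and IFI27 lost their calls with probes on at least 2 arrays (adjusted p = 0.0550 and 0.0624), RIGI also after removal of the local mean (0.0516) and IFI27 with its first probe (0.0953). ISG20 had a mean of 0.0860 after that removal. Drug transporters and metabolism gave 2 higher and 1 lower of 10, over all genes and adjusted over the list alone (camera adjusted p = 0.587). The aryl hydrocarbon receptor AHR rose by 0.283 ± 0.0145, and its target TIPARP by 0.202 ± 0.0239. CYP1B1, a further target of that receptor, averaged -0.0956 ± 0.0283 and lost its call with probes on at least 2 arrays (adjusted p = 0.0656) and after removal of the local mean (-0.0437, adjusted p = 0.341).

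Markers of cell identity did not pass as lists. Of 13 epithelial markers and keratins 4 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.581). The adhesion molecule EPCAM rose by 0.278 ± 0.0982 (n = 3) and the desmosomal protein DSP by 0.125 ± 0.0190, with KRT14 and DSC3. The keratin gene KRT18 fell to -0.159 ± 0.0328, against -0.10 (adjusted p = 0.134) with probes on at least 2 arrays. Mesenchymal markers had 4 higher and 0 lower of 15, over all genes and adjusted over the list alone (camera adjusted p = 0.581). The calponin CNN1, the repressor SNAI2 and the repressor ZEB2 rose by 0.269 ± 0.0251, 0.326 ± 0.0579 and 0.124 ± 0.0150, with TAGLN. ZEB2 averaged 0.104 (adjusted p = 0.0640) with probes on at least 2 arrays. Squamous differentiation had 1 higher and 3 lower of 12, over all genes and adjusted over the list alone (camera adjusted p = 0.510). S100A2 rose by 0.169 ± 0.0612, while the cystatin CSTB and CRCT1 fell to -0.167 ± 0.0368 and -0.149 ± 0.0385, with SLPI. Ciliated, secretory and alveolar markers had 2 higher and 2 lower of 11 (3 and 2 adjusted over the list alone, camera adjusted p = 0.587). The forkhead factor FOXA1 rose by 0.238 ± 0.0280, with 0.121 from its first probe, and the surfactant gene SFTPA1 by 0.207 ± 0.0812, with 0.130 after removal of the local mean. The mucin MUC5B fell to -0.230 ± 0.0319, with MUC4. With probes on at least 2 arrays MUC5B had an adjusted p of 0.0505. Blood and endothelial cell markers, included as markers of other cell types, had 0 higher and 2 lower of 6, over all genes and adjusted over the list alone (camera adjusted p = 0.558). Of all 9394 genes 29.0% were called, so these markers passed at about the general share. Whether their signal reflects expression could not be checked from ratios. CD4 averaged -0.0994 ± 0.0340, ITGAX -0.0855 ± 0.0176 and CD34 0.135 ± 0.145 (adjusted p = 0.139). CD4 and ITGAX lost their calls with probes on at least 2 arrays (adjusted p = 0.0663 and 0.0704). Array weights gave CD34 an adjusted p of 0.0430, and its mean was 0.192 (adjusted p = 0.0364) without array 3 and 0.0535 without array 1. Extracellular matrix and fibrosis had 3 higher and 5 lower of 23 (4 and 5 adjusted over the list alone, camera adjusted p = 0.587). The collagenase MMP1 rose by 0.192 ± 0.0138, with CCN1 and TAGLN, and had a mean of 0.117 after removal of the local mean. Tenascin C (TNC) and the collagen chain COL5A1 fell to -0.219 ± 0.0272 and -0.147 ± 0.0270, with COL4A2, LOXL2 and PLAU. In cholesterol and fatty acid synthesis 6 of 24 rose and 4 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.830). The sterol enzymes SC5D and SQLE rose by 0.203 ± 0.0355 and 0.188 ± 0.0270. FADS1, a fatty acid desaturase, fell to -0.177 ± 0.0242, although its 2 probes gave -0.309 and -0.0456 and the first of them did not pass (adjusted p = 0.187). FDPS, SREBF1 and EBP fell as well. Of the genes in this paragraph, KRT14, DSC3, TAGLN, SLPI, MUC4, CCN1, COL4A2, LOXL2, PLAU, FDPS, SREBF1 and EBP were named after their values were seen.

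In all, 5 of the 27 lists passed with the preset correlation, 2 of them higher and 3 lower. With a correlation estimated per list 0 passed by camera, with 2 at an unadjusted p under 0.05, and fry, which does not compare a list with other genes, passed 15, 10 higher and 5 lower. The median and the test had opposite signs for 3 lists, namely purine synthesis and salvage, DNA replication and G1/S, and heat shock proteins. In each of them the mean had the sign of the test. Without array 3 the number of lists that passed was 2.

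**Figure D2:**
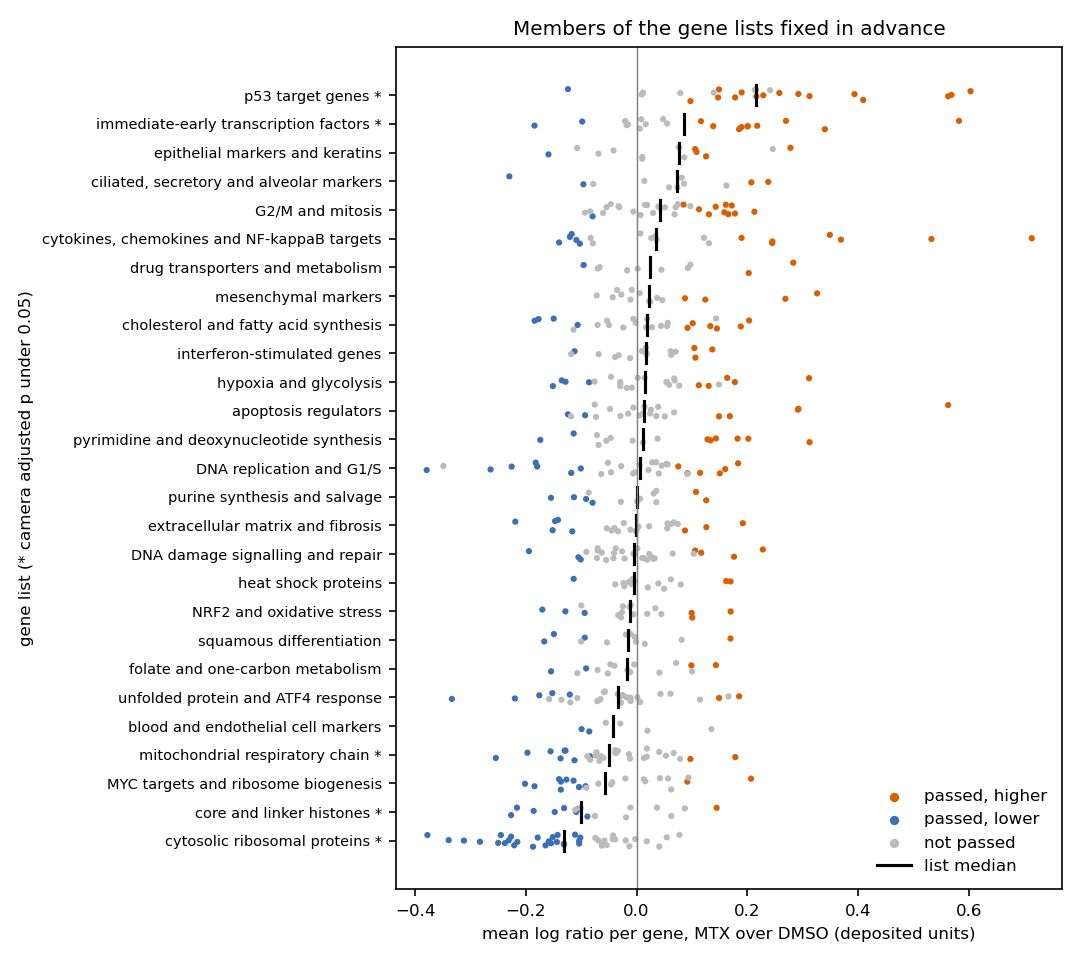
Mean log ratio of MTX over DMSO (x axis, deposited units, 3 arrays) for each measured member of the 27 gene lists (y axis), coloured by whether it passed higher, passed lower or did not pass, with a black bar at the list median. The p53 target genes have the median farthest to the right, 0.215, and the cytosolic ribosomal proteins the one farthest to the left, -0.131.

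The 3 arrays ran the same way but not equally closely. Across the 9394 genes, which are not independent replicates, arrays 1 and 2 had a Pearson correlation of 0.840, arrays 1 and 3 of 0.521 and arrays 2 and 3 of 0.588. TP53I3, KLK5, HOXC6 and HCRTR2 are examples of genes for which array 3 lay nearer to 0 than both other arrays. IL1B, FAS, PPM1D, HPRT1 and JUND had similar values on all 3.

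**Figure D3:**
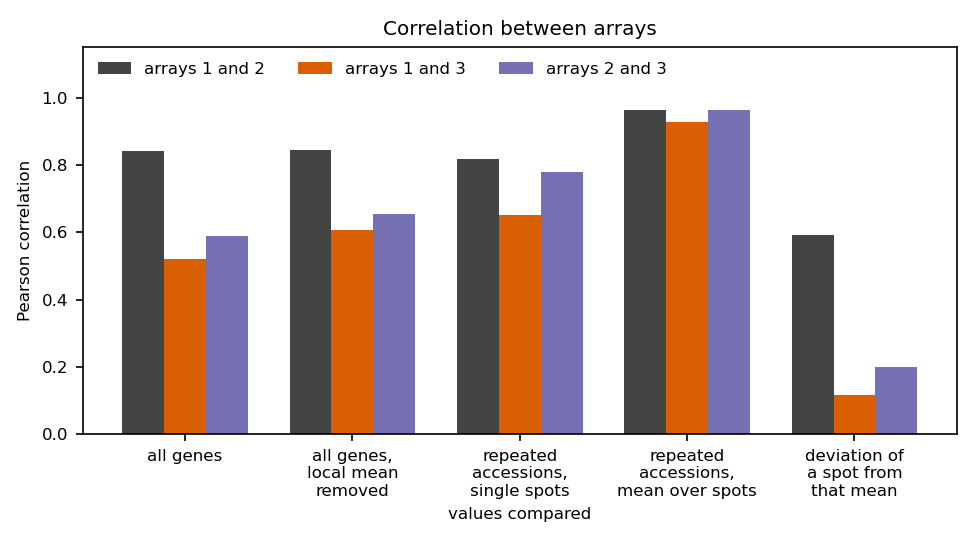
Pearson correlation (y axis) of log ratios for each pair of arrays (bars), over all genes, after removal of the local mean of the array surface, and over 554 spots of 56 repeated accessions as single spots, as means over spots and as deviations of a spot from that mean (x axis). Over all genes arrays 1 and 2 reach 0.840 and the pairs with array 3 reach 0.521 and 0.588, while the means over repeated spots reach 0.964, 0.927 and 0.962.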

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

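The removal of the local mean of the array surface and the average of arrays 1 and 2 were chosen after the data had been seen, as was the comparison of ribosomal proteins with abundant genes, and the other settings were planned. Against 2726 genes (1557 higher, 1169 lower) and 5350 probes, array weights gave 5801 genes (3176 higher, 2625 lower) and 11066 probes, and probes with values on at least 2 arrays gave 1633 genes (958 higher, 675 lower), of which 1500 were among the 2726. Leaving out 1 array gave 0 to 4287 genes, 0 to 2372 higher and 0 to 1915 lower, and 0 to 8250 probes. The 4287 came without replicate 3 and the 0 without replicate 1 or 2, where limma had 2938 and 2387 genes at an unadjusted p under 0.05. Without replicate 2, 704 probes were called. The average of arrays 1 and 2 left 0 genes (0 higher, 0 lower) and 0 probes, with 2786 genes at an unadjusted p under 0.05. Leaving out replicate 3 also left 2 arrays, yet gave 4287 genes, so the number of arrays is not the whole reason. In simulations of this size 2 arrays gave 0 calls. Those simulations used each gene's SD over all 3 arrays, so they cannot stand for arrays 1 and 2. The SAM-type test called 4173 genes (2532 higher), and a plain one-sample statistic 0 (0 higher, 0 lower), with 3025 at an unadjusted p under 0.05. Adjusted p under 0.10 gave 1788 lower genes and under 0.01 gave 227 (164 higher, 63 lower). Folds on the base 10 reading gave 124 (91 higher, 33 lower) with adjusted p under 0.05 and 2-fold, 404 (268 and 136) with treat against 1.2-fold, and 46 (37 and 9) with 2-fold on all 3 arrays. Centring, scaling, the robust spread model, the median or first probe and the local mean kept the counts within 1.5 times. After removal of the local mean 2094 of the 2726 genes were still called in the same direction.

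Of the 5 lists, p53 target genes (adjusted p 8.44e-10 to 2.21e-06) and cytosolic ribosomal proteins (3.80e-10 to 5.31e-08) passed without each replicate in turn. Histones ranged from 0.0105 to 0.0875, immediate-early factors from 0.00902 to 0.111 and the respiratory chain from 0.0289 to 0.0852, with the upper values without replicate 3. The number of lists that passed ranged from 2 to 7 without a replicate, was 0 with camera and an estimated correlation, and was 15 with fry. With the estimated correlation the adjusted p was 0.657 for p53 targets, 0.420 for ribosomal proteins, 0.667 for the respiratory chain and 0.732 for both histones and immediate-early factors. Against random lists the respiratory chain had an adjusted p of 0.0549. The MYC list passed with the first probe (0.0277), without the probes of widest range (0.0303), without replicate 1 (0.0469), after removal of the local mean (0.0275) and with fry (0.00726). The unfolded protein and ATF4 list passed with the median probe (0.0480) and 5 other settings. Lists that did not pass turned direction in 4 cases, hypoxia without the probes of widest range (adjusted p = 0.801) and after removal of the local mean (0.954), DNA damage with fry (0.758) and heat shock against random lists (0.875). The cause of these changes was not tested.

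Of the 103 named genes that were tested, 99 lost their call without replicate 1, without replicate 2 or with arrays 1 and 2 averaged, where 0 genes were called at all, and 19 lost it with probes on at least 2 arrays. The direction turned for 2 genes, SOD2 with its first probe (0.0109) and GGH, which had not passed, without replicate 3 (-0.000164). Over the fits that leave out 1 replicate GGH reached 0.0639, and after removal of the local mean it passed at 0.115. Correlations between arrays changed little on probes or by rank, and after removal of the local mean those with array 3 were 0.607 and 0.653, against 0.521 and 0.588 before. That of arrays 1 and 2 was 0.843, against 0.840. A filter on dim spots, background correction and a slide effect were not run, since signal over background was not used here.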

Other observations

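The classes below were chosen after the highest and lowest genes had been seen, and members already seen were left out of each test. An EGF receptor ligand class was planned too, but had no further measured member, and the class of initiation factors was narrowed by 3 kinase genes after its first result was known. As a hypothesis, genes of other classes may have shifted together. Zinc-finger genes of the ZNF series were higher, with 70 of 282 rising and 12 falling, a median of 0.0468 and a camera adjusted p of 0.000840 over the 6 classes (adjusted p = 0.116 with an estimated correlation). Of all 9394 genes 29.0% were called, 1557 higher and 1169 lower. The class thus differed in direction and not in the share of genes called. ZNF697 (0.305 ± 0.00836), ZNF451 (0.249 ± 0.00395) and ZNF217 (0.234 ± 0.00664) were examples (SD, n = 3). Mitochondrial ribosomal proteins, which build the ribosome inside mitochondria, were lower, with 24 of 64 falling and 1 rising, a median of -0.0704 and an adjusted p of 1.32e-05 (adjusted p = 0.116 with an estimated correlation). MRPL40 lay at -0.233 ± 0.0278 and MRPS15 at -0.160 ± 0.0125. The 65 other abundant genes, compared with ribosomal proteins below, had a median of -0.0611. A low reading of abundant transcripts was not tested for this class, nor was a dependence on signal level for the zinc-finger genes. Both classes passed again after removal of the local mean, at 0.000175 and 4.13e-06.

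Proteasome subunits had 12 of 32 genes lower and 3 higher, a median of -0.0427 and an adjusted p of 0.0633, against 0.00449 after removal of the local mean (adjusted p = 0.210 with an estimated correlation). PSMB10 and PSMB3 lay at -0.179 ± 0.0137 and -0.173 ± 0.00969. Translation initiation factors had 7 of 39 lower and 3 higher, a median of -0.0295 and an adjusted p of 0.0633. EIF3K and EIF4A1 fell to -0.173 ± 0.00704 and -0.205 ± 0.0373, and EIF4G2, known for translation without a cap, rose by 0.188 ± 0.0106. Aminoacyl-tRNA synthetases had a median of 0.00786 over 10 genes, with LARS1 lower at -0.127 ± 0.0194 (adjusted p = 0.673 for the class). Dual-specificity phosphatases had 4 of 14 genes higher and 1 lower, and a median of 0.0204 (adjusted p = 0.684). DUSP14 (0.322 ± 0.0517) and DUSP10 (0.315 ± 0.0921) rose and DUSP7 (-0.282 ± 0.129) fell, so these data do not show a shift of that class.

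All tests of the next pattern were chosen after it was seen. The bootstrap intervals here and below resample genes or accessions, so they do not measure the spread between arrays or cultures. Array 3 correlated less with arrays 1 and 2 (0.521 and 0.588) than these did with each other (0.840). Different RNA on array 3 stays open, since over 56 repeated accessions with 554 spots the mean differences between arrays spread 1.12 times as widely as the spots predict for arrays 1 and 2, and 1.26 and 1.195 times for the pairs with array 3, an excess of 0.103 (95% bootstrap interval -0.163 to 0.388). The gap between the correlations was 0.0199 (-0.00791 to 0.0452) on the means of these accessions and 0.103 (0.0366 to 0.175) on their single spots, which goes against it, but the means correlate at 0.927 to 0.964, where any gap is narrow, and it is not known whether the spots of an accession hold the same probe. A smooth trend over the surface is argued against as the whole cause, since 0.213 (0.197 to 0.229) of a gap of 0.286 was left after its removal. The local means themselves correlated at 0.828 between arrays 1 and 2. They correlated at 0.0862 between arrays 1 and 3 and at 0.228 between arrays 2 and 3. A surface pattern that arrays 1 and 2 share therefore stays open as a part of the cause. Deviations of single spots from their accession's mean correlated at 0.592 (0.449 to 0.696) between arrays 1 and 2, and at 0.118 (0.0190 to 0.225) and 0.199 (0.105 to 0.299) with array 3, so a candidate explanation is a technical deviation per spot that arrays 1 and 2 share, which would make their spread too small.

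Ribosomal protein genes were lower with MTX, and the test on the surface was chosen after this was seen. A surface trend is argued against, because the median was -0.119 (-0.166 to -0.0714) after its removal, against -0.131 before. A low reading of all abundant transcripts, which a dye or saturation effect could give without a dye swap, cannot be told apart. The 65 other abundant genes had a median of -0.0611 (-0.103 to -0.00742), an interval that holds values on both sides of what this explanation needs. By camera of limma these abundant genes lay below all other genes (p = 1.025e-05) and ribosomal proteins below the abundant genes (p = 0.00745), as they did by the medians (difference 0.0699, permutation p = 0.00896, 100000 resamples, two-sided), so the effect of MTX itself stays open, as does abundance for part of the shift.

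p53 target genes were higher with MTX, and both tests were chosen after this was seen. A surface trend and a single array are argued against as the whole cause, since the median was 0.208 (0.161 to 0.361) after removal of the local mean and at least 0.177 without each array in turn, against 0.215. A gene-specific dye effect was not tested, since no array has the dyes exchanged, and a response to MTX remains a hypothesis.

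The sign of the arrays allows 4 patterns, which are too few for a share under 0.05. As deposited, 2726 genes were called (1 of the 4 patterns reached this), and the highest count with 1 array turned was 0, with limma.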
